A study of Homo sapiens with 8 samples.

How the data were processed

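RNA of MCF-10F cells was measured on 8 Affymetrix human arrays: 2 of solvent controls, 4 of cells given 10 µM BPA and 2 of cells given 1 µM BPA, per the labels. The deposited values are log2 signals per probe set, made by the authors with RMA (background correction, quantile normalization between arrays and summary of probes into probe sets) and the affy package, per the submitters' processing notes. Their versions are not given in the sources used here. The values of the 8 arrays had array medians from 5.53 to 5.58, which was checked to fit log2 values normalized together. The original image intensities were not used here.

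Genes were named from the probe table of the series. Of 54613 probe sets, 41091 had 1 gene symbol, 1801 had several and 11721 were not listed. The gene IDs of 41037 probe sets were found in the human gene table used (assembly GRCh38.p14), which served for names and for the order of genes along chromosomes. Probe sets with several or no genes were left out of the comparisons. Each of 19775 genes was represented by the probe set with the highest mean over the 8 arrays, a choice that mattered for 10523 genes with more than 1 probe set. The 30% of genes with the lowest mean (5933 genes, mean log2 value under 5.20) were left out as dim, which left 13842. Some members of the gene lists were not analysed here. Quality control probe sets (0 of the values) were not part of the table, so the planned comparison of RNA quality from them was not run.

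A linear model of group means was fitted to the log2 values of all 8 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), so that the 3 groups shared an estimate of the spread. The contrasts were 10 µM against control, 1 µM against control and 10 µM against 1 µM. P-values were adjusted by the Benjamini-Hochberg method over the genes tested in each contrast, and genes were called at an adjusted p under 0.05. All fold changes are on the log2 scale with their standard errors from limma. A group mean under the dim limit was taken as not above background. For named genes with such a mean, a rule added after the values were seen, the change is a bound ("at least"): the other group's mean less the limit. This was so for 31 of 190 named genes at 10 µM, 30 of 193 at 1 µM and 3 of 64 between the doses. Gene lists (47 pathways and marker sets) were tested with camera from limma, with a preset correlation of 0.01 between genes and adjustment over lists, where at least 5 members were tested. That left 45 lists, since mismatch repair and neural markers had only 4 tested members each. Camera was also run with an estimated correlation, and fry was run as a test of each list alone. Members of a list were counted as called over all genes and adjusted over the list alone. Lists, tests, alternatives and the rule for naming genes were fixed before the data were examined. That rule took up to 8 called genes in each direction with the largest change at each dose, with all treated arrays on the same side of both controls, up to 5 in each direction between the doses, and up to 3 called members of each list with the smallest adjusted p. All members of the homologous recombination and receptor lists, BCL2L11, PDCD5 and the HOXC genes could be named with or without a call. BCL2L11, PDCD5 and the HOXC genes were included because they were known from the study, so they are not an independent choice.

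Overlap between the doses was set against the product of the list sizes over the number of genes, and against 20 simulations of unchanged groups sharing the 2 controls. Alternatives changed 1 choice at a time: a replicate block, arrays centred on their medians, cyclic loess, no filter or 50% of genes left out as dim, the mean of a gene's probe sets, all probe sets singly, other variance models, array weights, a fit of only the groups compared, stricter thresholds, and leaving out each array. After the results were seen, runs of neighbouring genes were sought with a running median of log2 fold changes over 51 genes (13804 genes with a known place), against the largest value anywhere in each of 200 shuffled orders. That search was repeated with a window of 25 genes on the brighter 6902 genes alone. This replaced a first test of dim probe sets, the median of the brighter genes inside the runs, because those genes had been picked for being lower. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

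The scripts were tested on simulated data with the real genes' means and spread and 200 changed genes. At 10 µM against control, 30.8% of genes changed by 0.5, 98.6% of those changed by 1 and 100% of those changed by 2 on the log2 scale were called, with 7 unchanged genes called among 13842. At 1 µM against control the shares were 11.8%, 85.9% and 100%, with 9 unchanged genes called, and between the doses 34.6%, 96.6% and 100%, with 8. In each contrast camera called the shifted list and 0 of the other lists. The simulated genes varied independently of each other, so this does not test list calls among correlated genes. The search for neighbouring genes found the planted run of 60 genes and no other among 13804 genes.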

Results

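Gene expression was measured on 8 Affymetrix human arrays in MCF-10F, an established line of non-tumorigenic human breast epithelial cells described in the study design as negative for oestrogen receptor alpha and progesterone receptor. Control cells received the solvent DMSO at 0.284% (2 arrays). Treated cells received bisphenol A (BPA), a plastics monomer that binds oestrogen receptors weakly, at 10 µM (4 arrays) or 1 µM (2 arrays) for 2 weeks. Cells at either dose had been collected after an invasion assay and expanded for 6 passages, and neither the labels nor the design state whether the control cells had the same history. Each comparison below therefore sets cells with the whole treatment history against the solvent controls. Each array gave values for 54613 probe sets, with array medians between 5.53 and 5.58 on the log2 scale. Every array correlated best with another array of its own group (8 of 8). Correlations across probe sets ran from 0.919 to 0.923 between control and 10 µM arrays, from 0.930 to 0.937 between control and 1 µM arrays, and from 0.971 to 0.979 between the doses. Within groups they were 0.991 (control), 0.989 (1 µM) and 0.996 to 0.997 (10 µM). The labels do not state where the replicates come from, so the p-values measure only the spread between these arrays, which may be technical, and the number of arrays limits the precision.

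Comparison of 10 µM BPA (n = 4 arrays) with control (n = 2) asks which transcripts differ in cells carried through exposure to the higher dose. Genes of the dividing cell were far higher in the BPA-treated cells. RRM2, the small subunit of ribonucleotide reductase, had a mean log2 value of 13.57 at 10 µM and rose by at least 8.37 on the log2 scale (higher in 4 of 4 arrays). Its control mean of 5.16 lay under 5.20, the limit below which genes were left out as dim, and changes against such a mean are given only as bounds. The proliferation marker MKI67 rose by 5.06 ± 0.09 SE, the spindle checkpoint kinase BUB1B by 5.03 ± 0.09 and the mitotic kinesin KIF20A by 4.88 ± 0.09 on the log2 scale. All 37 mitosis genes tested rose (mean of the list 6.64 in controls and 10.60 at 10 µM; camera adjusted p = 7.46e-21, or adjusted p = 0.0811 with an estimated correlation). Of 35 DNA replication genes, 34 rose and 1 was not called, among them UHRF1 (at least 5.84) and the replicative helicase component GINS1 (5.55 ± 0.10). The replication list had a median log2 fold change of 2.76 (camera adjusted p = 7.06e-17, or adjusted p = 0.0803 with an estimated correlation).

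**Figure D1:**
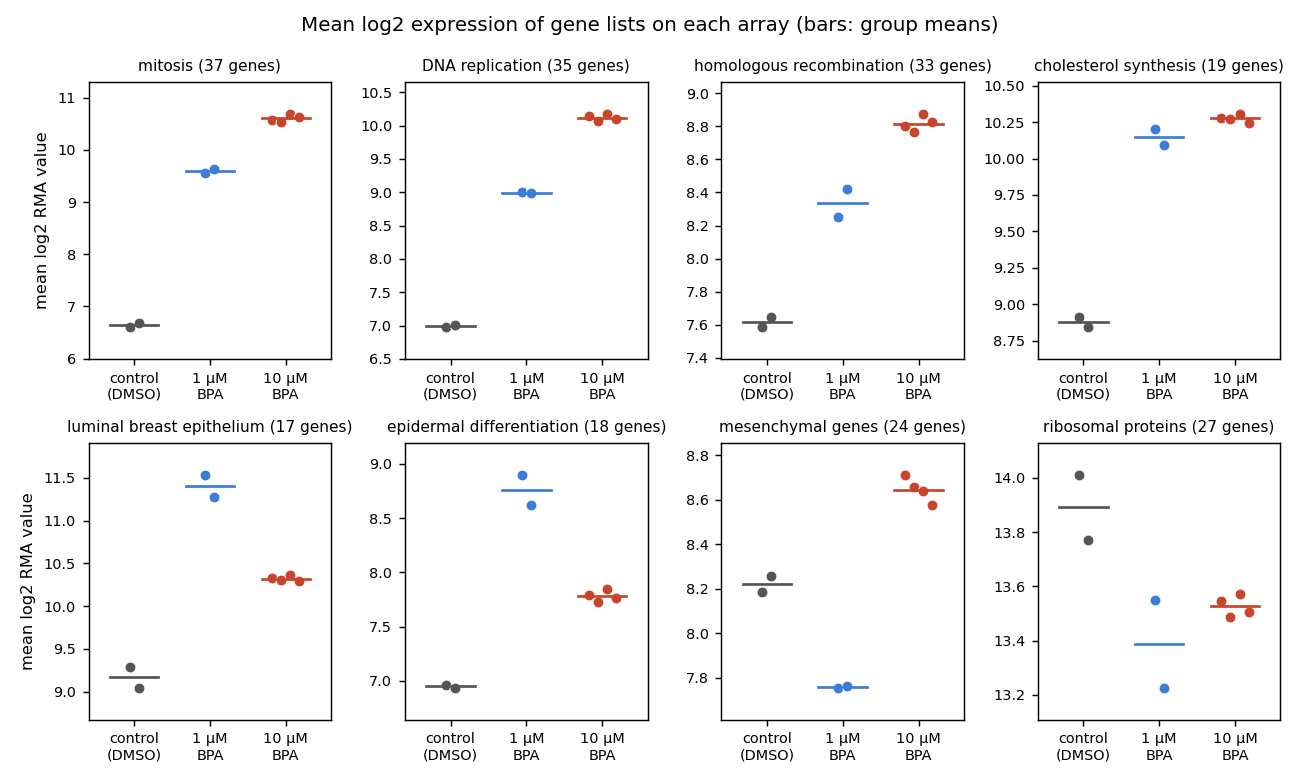
Mean log2 value of the tested members of each gene list shown, 1 point per array, for control, 1 µM BPA and 10 µM BPA. Mitosis genes averaged 6.64 in controls, 9.60 at 1 µM and 10.60 at 10 µM, and ribosomal protein genes averaged 13.89, 13.39 and 13.53.

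DNA repair is the subject named by the title of the study, and homologous recombination (the repair of broken DNA by copying an intact strand) was the main list fixed here. Since the title rests on these same samples, the list is not independent evidence of a direction. At 10 µM BPA, 23 of 33 homologous recombination genes tested rose, 4 fell and 6 were not called. Adjusted over the list alone, 24 rose and 4 fell. RAD51AP1 rose by at least 5.80 on the log2 scale. BRCA1, the breast cancer susceptibility gene whose product acts in this repair, rose from a mean log2 value of 6.11 to 10.16 (log2 fold change 4.05 ± 0.15, higher in 4 of 4 arrays, limma adjusted p = 1.32e-08). Its binding partners BARD1 (2.20 ± 0.12) and BRIP1 (2.80 ± 0.15), the resolvase gene GEN1 (at least 3.24), the helicase gene BLM (3.31 ± 0.14), NBN (1.67 ± 0.10) and BRCC3 (1.45 ± 0.11) also rose. The 4 that fell were RAD50 (-1.20 ± 0.11), which encodes a component of the break-sensing complex with NBN, RAD52 (-1.56 ± 0.14), and the BRCA1-A complex members ABRAXAS1 (-1.87 ± 0.17) and UIMC1 (-1.10 ± 0.10). MRE11 had a log2 fold change of 0.05 ± 0.13 (limma adjusted p = 0.785) and was not called. The call of BABAM1 was kept without control replicate 2, with its log2 fold change at 0.64 in place of 0.98. PALB2 (0.39) and XRCC3 (0.32) lost their calls when single arrays were left out. PALB2 lost it without control replicate 2 (0.19) and 10 µM replicates 2 (0.39) and 3 (0.36). XRCC3 lost it without control replicate 1 (0.24) and 10 µM replicates 1 (0.33), 2 (0.32) and 4 (0.27). With centred arrays neither was called (PALB2 0.25, adjusted p = 0.111, and XRCC3 0.18, adjusted p = 0.242), nor was PALB2 with cyclic loess (0.32, adjusted p = 0.0556). The list had a median log2 fold change of 1.00 and a mean on each treated array above both controls (camera adjusted p = 0.00116, or adjusted p = 0.395 with an estimated correlation).

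**Figure D2:**
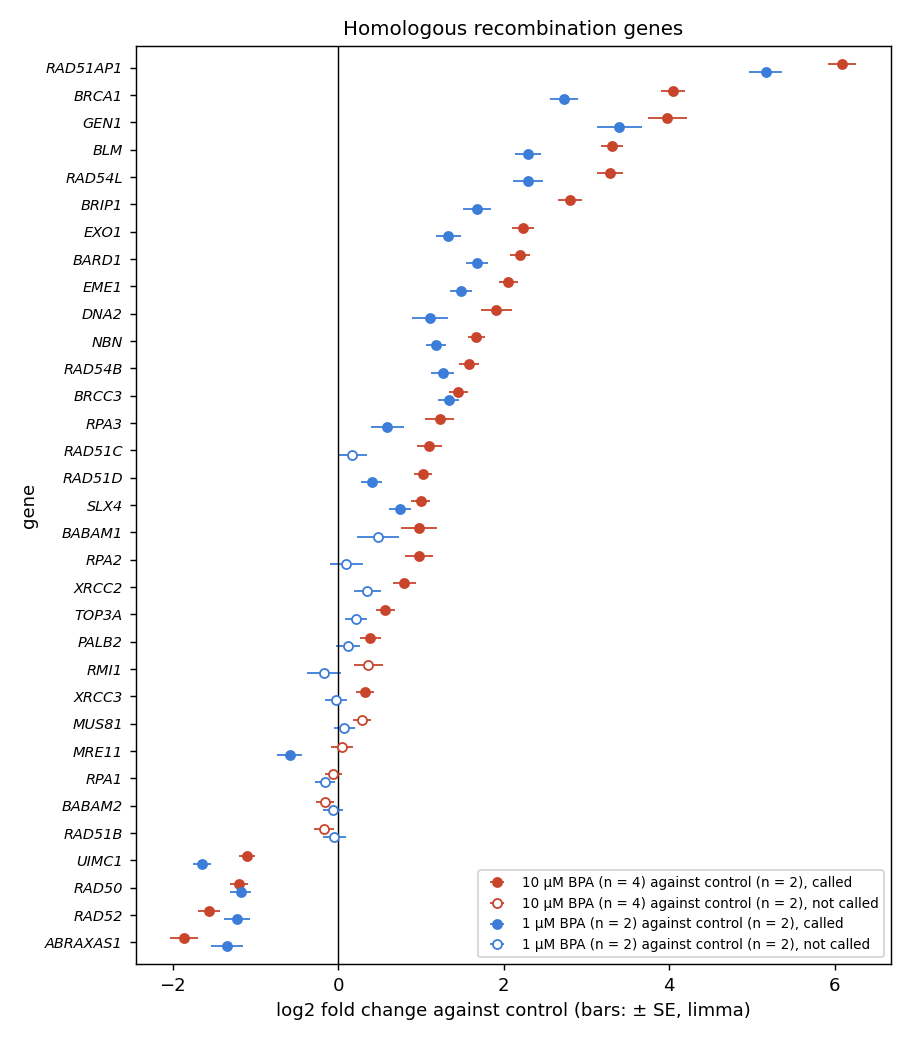
Log2 fold change against control (horizontal axis, with 1 SE) of each homologous recombination gene tested, at 10 µM BPA (n = 4 arrays) and 1 µM BPA (n = 2), each against the same 2 controls. RAD51AP1 is drawn highest, at 6.09 and 5.17, and GEN1 at 3.98 and 3.40. Both have a control mean under the dim limit, so only the bounds given in the text hold for them. RAD50, RAD52, ABRAXAS1 and UIMC1 lie below 0 at both doses.

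Genes of damage signalling rose as well at 10 µM, with 12 of 16 higher, 1 lower and 3 not called (median 0.75; camera adjusted p = 0.00736, or adjusted p = 0.395 with an estimated correlation). H2AX, the histone variant phosphorylated at DNA breaks, rose by 3.24 ± 0.15 and the fork protection gene TIMELESS by 3.16 ± 0.17. Targets of p53 went the other way, with 14 of 22 lower and 6 higher (median -0.59; camera adjusted p = 0.0403, or adjusted p = 0.395 with an estimated correlation). SESN1 fell by 2.50 and XPC by 2.11 on the log2 scale, while TIGAR rose by 1.83 ± 0.11. The p53 call was lost without control replicate 1 (median -0.59, adjusted p = 0.0733) and with arrays centred on their medians (adjusted p = 0.0777). DNA methylation genes rose in 12 of 15 cases with 1 lower, led by UHRF1 and the maintenance methyltransferase DNMT1 (3.45 ± 0.09), with a list median of 1.26 (camera adjusted p = 0.00182, or adjusted p = 0.386 with an estimated correlation). UHRF1 also belongs to the replication list, so the methylation list is not separate from it. Whether a larger share of dividing cells lies behind the changes of the damage signalling and methylation lists was not tested at either dose. Ribosome biogenesis genes rose in 15 of 20 cases with 1 lower (NOP2 1.59 ± 0.10, RRS1 2.42 ± 0.15; list median 1.20; camera adjusted p = 0.00197, or adjusted p = 0.395 with an estimated correlation). In contrast, 15 of 27 ribosomal protein genes fell and none rose (RPS27 -1.01 ± 0.09, RPL19 -0.92 ± 0.10; list median -0.34; camera adjusted p = 0.00499, or adjusted p = 0.585 with an estimated correlation). Of 7 histone genes tested, 5 fell and 1 rose (H2BC5 -2.85 ± 0.11; list median -1.66; camera adjusted p = 0.0403, or adjusted p = 0.395 with an estimated correlation). Other members, among them H1-3, H1-4, H2AC8 and H4C8, were left out as dim, so these genes do not stand for all histone transcripts. The histone call was lost without control replicate 1 (median -1.83, adjusted p = 0.0534) and under other array scalings (adjusted p = 0.0513 with cyclic loess and 0.0741 with centred arrays).

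Cholesterol synthesis genes rose in 14 of 19 cases with none lower (INSIG1 2.97 ± 0.11, IDI1 2.81 ± 0.12, HMGCS1 2.88 ± 0.13; list median 1.56; camera adjusted p = 4.24e-05, or adjusted p = 0.0811 with an estimated correlation). Targets of the growth factor TGF-beta rose in 10 of 19 cases and fell in 3 (list median 1.11; camera adjusted p = 0.00736, or adjusted p = 0.395 with an estimated correlation), including TGFB2 itself (at least 3.16), PMEPA1 (4.31 ± 0.14) and CCN2 (at least 4.04). Actin and YAP target genes rose in 15 of 23 cases and fell in 3 (camera adjusted p = 0.0143, or adjusted p = 0.413 with an estimated correlation), with F3 at 5.87 ± 0.10 and the receptor kinase AXL at -3.43 ± 0.12. Interferon response genes fell in 16 of 26 cases and rose in 6 (IFIT1 -3.87 ± 0.11, IFIT2 -3.59 ± 0.19; list median -0.84; camera adjusted p = 0.0101, or adjusted p = 0.395 with an estimated correlation). Luminal epithelial markers rose in 10 of 17 cases and fell in 2 (AGR2 at least 3.75, ALDH1A3 2.81 ± 0.11; camera adjusted p = 0.0403, or adjusted p = 0.395 with an estimated correlation), a call that cyclic loess scaling ended (adjusted p = 0.0513). Epithelial junction genes rose in 15 of 26 cases and fell in 5 (CGN 2.79 ± 0.11, CLDN1 -1.94 ± 0.12; camera adjusted p = 0.045, or adjusted p = 0.386 with an estimated correlation). The junction call was lost without control replicate 2 (median 0.64, adjusted p = 0.0535), without 10 µM replicate 2 (median 0.72, adjusted p = 0.0538), with cyclic loess (adjusted p = 0.0645) and with 50% of genes left out as dim (adjusted p = 0.0994). The basal keratin KRT14 rose by 5.83 ± 0.30, but the basal list was not called. Its members DSC3 (-2.93 to -1.47) and MME (-2.43 to -1.415) were lower in every probe set. Adjusted over the list alone, the counts of the lists named for this dose were the same, except for 14 ribosomal protein genes and 6 junction genes lower and 11 TGF-beta targets higher.

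Large increases, not ranked because the controls lay under the dim limit, included the matrix protein gene EDIL3 (at least 5.64), the growth factor binding protein gene FGFBP1 (at least 7.56) and the cobalamin binding protein gene TCN1 (at least 6.71). Large decreases to a mean under that limit included the glycosyltransferase gene GALNT15 (by at least 7.43), the oestradiol-inactivating enzyme gene HSD17B2 (6.58), BASP1 (6.61) and RTN1 (5.81). Single markers of other cell types moved in both directions at 10 µM. Of the leukocyte genes LAPTM5 fell by 7.14 and CD14 by 3.88, while CORO1A rose by at least 2.18. Of the fibroblast genes DCN fell by 4.38 and FAP rose by 4.27 ± 0.14 on the log2 scale. Across all genes tested, limma called 8096 of 13842 (58.5%), 4311 higher and 3785 lower, of which 2021 and 1641 changed at least 2-fold. With arrays centred on their medians the split was 3606 higher and 4593 lower (44.0% higher against 53.2%). The median log2 fold change of all genes moved from 0.04 to -0.10 with it. No list called on the deposited scale changed direction with that shift.

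Receptor genes, including those of receptors that BPA is known to bind, moved in both directions. ESR1 (log2 fold change 0.15 ± 0.10, limma adjusted p = 0.236) and ESR2 (0.00 ± 0.15, adjusted p = 0.983) were not called, and their mean log2 values of 6.33 and 5.91 in controls lay not far above the limit of 5.20 below which genes were left out as dim. GPER1 was called at 0.39 ± 0.12, but not without control replicate 2 (0.27, adjusted p = 0.148), with centred arrays (adjusted p = 0.0981) or with the mean of probe sets (0.18, adjusted p = 0.115). The adipogenic receptor PPARG rose by 1.51 ± 0.11 at 10 µM and 1.01 ± 0.12 at 1 µM. ARNT, the partner of the aryl hydrocarbon receptor, fell by 3.09 and 1.51 on the log2 scale. The glucocorticoid receptor gene NR3C1 fell by 0.91 and 0.72. The thyroid hormone receptor gene THRB fell by 1.42 at 10 µM and had a log2 fold change of -0.02 ± 0.14 at 1 µM, and the difference between the doses was called (-1.39 ± 0.12, limma adjusted p = 2.82e-05). Of 11 receptor genes tested, 3 rose, 4 fell and 4 were not called at 10 µM, and the list was not called (camera adjusted p = 0.676). The calls of AHR (0.46) and THRA (-0.44) at 10 µM were lost without control replicate 1 (0.29 and -0.26), and that of AHR also without 10 µM replicates 3 (0.44) and 4 (0.42). With centred arrays AHR was not called (0.33, adjusted p = 0.0928), and with the mean of probe sets THRA was not (-0.16, adjusted p = 0.109). Among regulators of apoptosis, BCL2L11, a promoter of cell death, fell by 1.85 (± 0.11 SE) at 10 µM and by 0.68 (± 0.12) at 1 µM on the log2 scale. HRK, of the same BH3-only class, fell by 4.25 and 3.12. Other members went up at 10 µM: BID, also of that class, by 1.63 to 2.26 over its 3 probe sets, and FADD by 1.79. PDCD5 gave a log2 fold change of 0.71 ± 0.26 at 10 µM (limma adjusted p = 0.0398) from its brighter probe set, while its other probe set gave -2.65 and the mean of both -0.97. Its call was also lost without control replicate 2 (0.32, adjusted p = 0.385) and with each of 10 µM replicates 1, 3 and 4 left out (0.70, 0.63 and 0.75) and with centred arrays (0.58, adjusted p = 0.0669), and it stood at 1.10 without control replicate 1. The apoptosis list held 7 genes higher and 11 lower of 25 and was not called (camera adjusted p = 0.448). In the HOXC cluster, HOXC13 fell by 1.11 (± 0.11) and HOXC9 rose by 0.55 ± 0.11, whereas HOXC10 (0.09 ± 0.10) and HOXC11 (0.08 ± 0.10) were not called.

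Comparison of 1 µM BPA (n = 2 arrays) with control (n = 2) puts the same question for the lower dose. Division genes were again higher, with MKI67 up by 4.03 ± 0.10, BUB1B by 4.27 ± 0.11 and RRM2 by at least 7.42 on the log2 scale (each higher in 2 of 2 arrays). All 37 mitosis genes rose (median 2.85; camera adjusted p = 4.42e-21). So did 33 of 35 replication genes with 2 not called (median 1.43; camera adjusted p = 3.97e-13). Luminal markers rose in 15 of 17 cases and fell in 1 (median 1.80; camera adjusted p = 5.88e-06), among them the secretory pathway gene AGR2 (at least 7.72), ALDH1A3 (3.70 ± 0.13) and the luminal transcription factor FOXA1 (at least 3.86). Epithelial junction genes rose in 18 of 26 cases and fell in 2 (CGN 3.45 ± 0.13, GRHL1 3.30 ± 0.19; median 1.06; camera adjusted p = 0.000132). Cholesterol synthesis genes rose in 16 of 19 with none lower (INSIG1 2.88 ± 0.13; median 1.21; camera adjusted p = 6.97e-06). These 5 lists kept their calls with an estimated correlation (adjusted p = 0.0476 for each).

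At 1 µM, homologous recombination genes rose in 16 of 33 cases, fell in 5 and were not called in 12, and the counts were also 16 and 5 adjusted over the list alone. RAD51AP1 rose by at least 4.88, GEN1 by at least 2.66, BRCA1 by 2.73 ± 0.17 and BARD1 by 1.68 ± 0.13, while UIMC1 fell by 1.65 and RAD50 by 1.18 on the log2 scale. The list median was 0.40 (camera adjusted p = 0.0477, or adjusted p = 0.642 with an estimated correlation). That call was lost without 1 µM replicate 2 (0.36, adjusted p = 0.0827), with cyclic loess (0.39, adjusted p = 0.0605) and with 50% of genes left out as dim (0.48, adjusted p = 0.166), and with arrays centred on their medians the median was 0.22 with the call kept. The calls of MRE11 (-0.58), RAD51D (0.40) and RPA3 (0.59) were lost without single arrays. Without 1 µM replicate 1, MRE11 stood at -0.36 and RPA3 at 0.31. Without control replicate 2, MRE11 stood at -0.47, RPA3 at 0.38 and RAD51D at 0.35. RAD51D stood at 0.36 without 1 µM replicate 2. With centred arrays RAD51D (0.22, adjusted p = 0.169) and RPA3 (0.42, adjusted p = 0.0916) were not called, nor was RPA3 with cyclic loess (0.50, adjusted p = 0.0689). Epidermal differentiation genes rose in 12 of 18 cases and fell in 2 (KLK7 4.93 ± 0.14, SPRR1A at least 4.01; median 1.57; camera adjusted p = 0.000436, or adjusted p = 0.184 with an estimated correlation). Glycolysis and hypoxia genes rose in 20 of 30 cases and fell in 1 (EGLN3 2.41 ± 0.12, PGK1 1.89 ± 0.12; median 0.82; camera adjusted p = 0.000143, or adjusted p = 0.388 with an estimated correlation). DNA methylation genes rose in 11 of 15 and fell in 1 (camera adjusted p = 0.000332, or adjusted p = 0.188 with an estimated correlation). Ribosomal protein genes fell in 16 of 27 cases with none higher (median -0.51, and -0.32 without 1 µM replicate 2; camera adjusted p = 0.000105, or adjusted p = 0.554 with an estimated correlation). Targets of p53 fell in 12 of 22 cases and rose in 2 (SESN1 -2.23 ± 0.12, but TP53I3 3.57 ± 0.25; camera adjusted p = 0.00647, or adjusted p = 0.188 with an estimated correlation). TGF-beta targets rose in 10 of 19 and fell in 3 (INHBA at least 4.01; median 1.15; camera adjusted p = 0.0487, or adjusted p = 0.579 with an estimated correlation). The TGF-beta call was lost without control replicate 2 (median 1.03), without 1 µM replicate 1 (1.21) or 2 (0.98), with cyclic loess (1.19), with 50% of genes left out as dim (1.17) and with the mean of probe sets (0.43). Adjusted over the list alone, the counts of the lists named so far for this dose were the same except for 16 luminal, 20 junction, 12 methylation and 3 p53 genes higher and 4 TGF-beta targets lower.

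Lists called at 10 µM but not at 1 µM were damage signalling (5 higher and 2 lower of 16, camera adjusted p = 0.29), ribosome biogenesis (6 and 3 of 20, adjusted p = 0.846) and interferon response (3 and 12 of 26, adjusted p = 0.0588). The same held for actin and YAP targets (12 and 4 of 23, adjusted p = 0.196) and histones (1 and 4 of 7, adjusted p = 0.284). Of all these, interferon response was the only list that camera did not call between the doses. With adjustment over the list alone, 4 interferon genes were higher and 13 lower, and 5 actin and YAP targets were lower. Mesenchymal genes at 1 µM fell in 11 of 24 cases and rose in 5 without a call for the list (camera adjusted p = 0.0908). The intermediate filament gene VIM fell by 4.31 (± 0.20) and the transcription factor gene TWIST1 by 3.16 (± 0.14) on the log2 scale. Large increases at this dose included TCN1 (at least 8.94), the amino acid transporter gene SLC6A14 (at least 7.86), FGFBP1 (at least 8.38) and IGFBP3 (7.90 ± 0.15). Large decreases included GALNT15 (by at least 7.43), HSD17B2 (by at least 6.58), the transcription factor gene SOX7 (by at least 5.53) and SLC7A2 (-7.01 ± 0.16). Of the markers of other cell types, LYZ rose by at least 2.75 and PECAM1 by 3.06 ± 0.13, while LAPTM5 fell by 5.81 and DCN by 4.32. In total limma called 6667 of 13842 genes (48.2%), 3715 higher and 2952 lower, with 1775 and 1124 changed at least 2-fold. This count rests on a spread shared with the 10 µM arrays, which varied least. The median gene SD was 0.10 at 10 µM, 0.13 in controls and 0.17 at 1 µM. A fit of only control and 1 µM called 4673 genes, and array weights gave 5131. With arrays centred on their medians the split was 2922 higher and 4237 lower (40.8% higher against 55.7%). The median log2 fold change of all genes moved from 0.02 to -0.16. That shift turned the direction of none of the lists called.

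The 2 comparisons with control shared most of their direction. At both doses 2990 genes were higher than in controls, where independent lists of these sizes would share 1157, and 2469 were lower, where they would share 807. Only 214 genes called at both doses went in opposite directions, 59 of them higher at 10 µM and lower at 1 µM. Across genes, which are not independent replicates, the log2 fold changes correlated with r = 0.852, against 0.575 for simulated unchanged groups sharing the 2 controls, and their covariance was 1.12 against 0.0144. In the 20 simulations no gene was called at both doses, but in unchanged groups almost none could be. That count therefore does not measure what the shared controls add among changed genes. Part of the excess over independent lists may come from the shared controls, which are too few to split. Among the genes higher at both doses, 996 were higher at 10 µM than at 1 µM, 554 were lower and 1440 were not called apart. BRCA1, MKI67 and CCN2 were among those higher at 10 µM (BRCA1 1.31 ± 0.15 between the doses), whereas TCN1 and AGR2 reached higher levels at 1 µM (mean log2 values 14.14 and 12.92 at 1 µM against 11.91 and 8.95 at 10 µM).

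**Figure D3:**
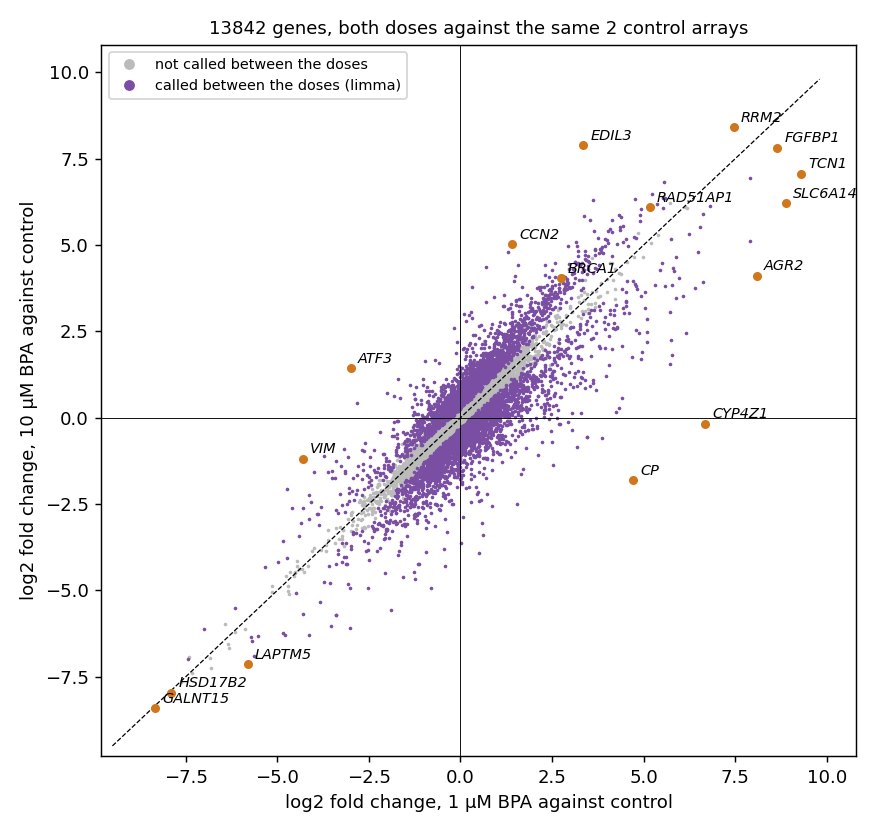
Log2 fold change at 1 µM BPA (horizontal axis) and at 10 µM BPA (vertical axis), each against the same 2 control arrays, with 1 point per gene tested (13842 genes). Most genes lie along the diagonal (r = 0.852 across genes), to which the shared controls may add.

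Comparison of the doses, 10 µM (n = 4) against 1 µM (n = 2), does not use the levels of the controls, which enter only the estimate of the spread. Cells at 10 µM had more transcript of division, homologous recombination and damage signalling genes and less of luminal and epidermal genes. All 37 mitosis genes were higher at 10 µM (median 1.03; camera adjusted p = 2.14e-17, or adjusted p = 0.101 with an estimated correlation). So were 34 of 35 replication genes (median 1.08; camera adjusted p = 7.84e-18, or adjusted p = 0.0681 with an estimated correlation). Homologous recombination genes were higher in 20 of 33 cases and lower in 1 (BRIP1 1.12 ± 0.15; median 0.52; camera adjusted p = 3.61e-05, or adjusted p = 0.241 with an estimated correlation), or in 22 and 2 when adjusted over the list alone. Within it, RAD51AP1 (0.93) stood at 0.61 without 1 µM replicate 1, and the calls of DNA2 (0.80), RMI1 (0.53), XRCC2 (0.45), XRCC3 (0.35) and TOP3A (0.36) were lost there (0.46, 0.17, 0.35, 0.35 and 0.31). RMI1 also lost its call without each 10 µM array (0.50 to 0.58), as did TOP3A (0.34 to 0.38). XRCC2 lost it without 10 µM replicates 1 (0.44), 2 (0.36) and 3 (0.46), and XRCC3 without 1, 2 and 4 (0.35, 0.34 and 0.30). The lower gene, ABRAXAS1 (-0.52), lost its call without 10 µM replicates 1 (-0.52), 2 (-0.43) and 4 (-0.56). Without 1 µM replicate 2, ABRAXAS1 (-0.33, adjusted p = 0.242), XRCC3 (0.35), TOP3A (0.40) and RPA3 (0.35) were not called. TOP3A was also not called with cyclic loess (0.35, adjusted p = 0.0536) or the mean of probe sets (0.22, adjusted p = 0.0637). Damage signalling genes were higher in 9 of 16 with none lower (camera adjusted p = 0.000906, or adjusted p = 0.241 with an estimated correlation; 11 adjusted over the list alone). Ribosome biogenesis genes were higher in 18 of 20 with none lower (median 0.94; camera adjusted p = 1.29e-08, or adjusted p = 0.12 with an estimated correlation). Luminal markers were lower in 11 of 17 and higher in 1 (median -0.78; camera adjusted p = 0.000191, or adjusted p = 0.101 with an estimated correlation). Epidermal genes were lower in 11 of 18 and higher in 1 (median -0.997; camera adjusted p = 0.00019, or adjusted p = 0.118 with an estimated correlation). Junction genes were lower in 13 of 26 and higher in 1 (camera adjusted p = 0.000191), and mesenchymal genes higher in 13 of 24 and lower in 2 (camera adjusted p = 0.000191), each with adjusted p = 0.101 with an estimated correlation. Adjusted over the list alone, 2 luminal and 14 mesenchymal genes were higher and the other counts of these 4 lists were the same.

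EDIL3 (4.55 ± 0.11), the stress-induced transcription factor gene ATF3 (4.44 ± 0.23), the proteoglycan gene VCAN (3.66 ± 0.24) and CCN2 (3.62 ± 0.18) were the most raised at 10 µM over 1 µM. Much lower at 10 µM were the mammary cytochrome gene CYP4Z1 (by at least 6.00), the ceruloplasmin gene CP (by at least 5.38), the peptide transporter gene SLC15A2 (by at least 4.05) and the prostaglandin-degrading enzyme gene HPGD (-4.41 ± 0.18). CYP4Z1 lay under the dim limit in controls and at 10 µM, against a mean log2 value of 11.19 at 1 µM. BCL2L11 was lower at 10 µM by its brightest probe set (-1.17 ± 0.11), but its mean over probe sets differed by only -0.08 (adjusted p = 0.567). In total limma called 5251 of 13842 genes between the doses (37.9%), 2453 higher and 2798 lower at 10 µM, with 514 and 806 changed at least 2-fold. With arrays centred on their medians the majority turned, to 2743 higher and 2557 lower (51.8% higher against 46.7%), so neither direction is taken to prevail.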

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

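The tests of dividing cells, other cell types and mislabelling in this part were chosen after the results were seen. The fits with cyclic loess and centred arrays were fixed before the data were examined, and only their use on the question of scaling was chosen afterwards.

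The difference between the doses passed its own test for many genes and, by camera with the preset correlation, for 19 lists. None of these 19 was called with an estimated correlation (adjusted p = 0.0681 for DNA replication to adjusted p = 0.376 for laminins, collagens and integrins). Limma called 5251 genes between 10 µM and 1 µM, and 214 genes called at both doses went in opposite directions against control. Lists higher at 10 µM than at 1 µM by camera were DNA replication (median log2 difference 1.08), mitosis (1.03), ribosome biogenesis (0.94), homologous recombination (0.52), damage signalling (0.48), mesenchymal genes (0.42) and basal markers (0.43; 9 of 18 higher, adjusted p = 0.0117, or adjusted p = 0.127 with an estimated correlation). Also higher were actin and YAP targets (0.43; 9 of 23, adjusted p = 0.000524), inflammatory cytokines (0.59; 11 of 22, adjusted p = 0.00813) and immediate-early genes (0.37; 12 of 22, adjusted p = 0.00395). The same held for base excision repair (0.31; 9 of 19, adjusted p = 0.0138), Fanconi anaemia genes (0.68; 7 of 10, adjusted p = 0.0287), TGF-beta targets (0.34; 7 of 19, adjusted p = 0.0369) and laminins, collagens and integrins (0.24; 10 of 28, adjusted p = 0.043). With an estimated correlation the 7 lists from actin to laminins had, in that order, adjusted p = 0.241, 0.241, 0.116, 0.337, 0.241, 0.36 and 0.376. Lists lower at 10 µM were epidermal differentiation (-0.997), luminal markers (-0.78), epithelial junctions (-0.46), glycolysis and hypoxia (-0.45; 16 of 30, adjusted p = 0.000315, or adjusted p = 0.241 with an estimated correlation) and histones (-0.76; 3 of 7, adjusted p = 0.0287, or adjusted p = 0.263 with an estimated correlation). Adjusted over the list alone, 11 actin, 14 immediate-early, 10 base excision repair and 9 TGF-beta genes were higher.

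Several of these list calls rested on single arrays. Without 1 µM replicate 1 the calls of Fanconi anaemia genes (0.64), histones (-0.32), TGF-beta targets (0.28) and laminins, collagens and integrins (0.23) were lost, and the medians of glycolysis (-0.28) and base excision repair (0.48) moved with their calls kept. Base excision repair lost its call without 1 µM replicate 2 (0.25), TGF-beta targets without either control (0.34), and laminins, collagens and integrins without 10 µM replicate 1 (0.22) or 2 (0.25). Other choices ended calls as well. With centred arrays TGF-beta targets (0.38) and laminins, collagens and integrins (0.28) had adjusted p = 0.052 each. With 50% of genes left out as dim, Fanconi anaemia genes (0.62, adjusted p = 0.101), histones (-0.79, adjusted p = 0.0659) and laminins, collagens and integrins (0.38, adjusted p = 0.0826) were not called.

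The homologous recombination genes stood higher at 10 µM than in controls, in cultures whose division genes were higher too. A larger share of dividing cells may account for part of this: the 10 members known to peak in dividing cells, such as BRCA1 and RAD51AP1, had a median log2 fold change of 2.52, and the other 23 members 0.39 (quartiles -0.11 and 1.06). Of those 23, 13 were called higher and 4 lower. The 10 members were picked from textbook knowledge, so genes among the 23 may rise with division too. The split therefore cannot decide whether a shift in that share covers the whole list. The list kept its call under other array scalings, with a median of 1.00 with cyclic loess (0.9961) and 0.86 with centred arrays. The deposited values were already normalized between arrays, so cyclic loess could change little and does not decide whether scaling plays a part. Whether BPA, the invasion assay, the later passages or the confluence of the control cultures set the share of dividing cells was not tested, and the design gives no group that would separate them.

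A large share of the genes tested was called against control at each dose (58.5% at 10 µM and 48.2% at 1 µM). Cyclic loess gave 8150 genes at 10 µM and centred arrays 8199, but the values were already normalized between arrays, so scaling stays open. A single mislabelled array is argued against, since 8 of 8 arrays correlated best with their own group. Admixture of fibroblasts, leukocytes, endothelial cells, neural cells or hepatocytes, in the controls or at both doses, is argued against as the whole cause. At most 11.1% of the markers of any of these differed by 1 or more in the same direction at both doses. Admixture at 1 dose alone was not tested, because the test asked for a change at both. Luminal breast markers, higher in 10 and 15 of 17 cases, were not in that test, so another share of luminal-like epithelial cells stays open. Open and untested are the exposure itself, the selection by the invasion assay, the 6 passages and clonal differences between cultures, which all go with the groups.

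Of 237 named genes, 6 (2.53%) had a 10 µM array far from the other 3, measured as its gap to the nearest over the range of the group and set against Dixon's critical value, which chance passes in about 1 in 20 groups. These were FADD (0.846), HOXB6 (0.93), IL24 (0.877), NDRG1 (0.879), NOTCH1 (0.871) and BID (0.864), and none of the 45 lists met the same limit. Among 11721 probe sets without a listed gene, which enter no comparison of genes, 1148 were higher and 1931 lower at 10 µM than in controls, and 847 higher and 1596 lower at 1 µM. Among 1801 probe sets with several genes, 360 were higher and 393 lower at 10 µM, and 247 higher and 319 lower at 1 µM.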

How the results depend on the processing

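The alternatives in this part were all planned. Counts of genes called stayed within 1.5 times under each alternative except the added 2-fold limit, which by its construction left fewer: 3662, 2899 and 1320 for 10 µM against control, 1 µM against control and 10 µM against 1 µM. Leaving out each array gave 7220 to 8663, 5903 to 6651 and 4429 to 5569 genes, and 4761 to 5542 shared by the doses in direction. Without a control or a 1 µM array, 1 array remained and was assumed to vary like the other groups. Lists called numbered 0, 5 and 0 with an estimated correlation in camera (5, 8 and 9 at an unadjusted p under 0.05) and 40, 33 and 38 with fry, which does not compare a list with other genes. Leaving out each array gave 13 to 16, 10 to 13 and 16 to 20 lists. The homologous recombination median at 10 µM was 0.92 to 1.08 with each array left out and kept its call, except with an estimated correlation (0.996, adjusted p = 0.395). At 1 µM it lost its call with cyclic loess (0.3861), with 50% of genes left out as dim (0.4815), with an estimated correlation (0.4034, adjusted p = 0.642) and without 1 µM replicate 2 (0.3649), within a range of 0.3285 to 0.4551 over the arrays left out. The cause of these losses was not tested. Its adjusted p over all alternatives reached from 0.000461 with fry to 0.642. PDCD5 reversed to -0.9666 with the mean of probe sets, because its probe sets went in opposite directions. Of 383 gene results, 350 kept their call and 33 lost it under at least 1 of the alternatives run for single genes: the replicate block, the other scalings, the other filters, the mean of probe sets and each array left out. The groups share replicate numbers, and a replicate block gave 7492, 6594 and 4607 genes, 5170 shared in direction, 14, 13 and 20 lists, and homologous recombination medians of 0.9944 and 0.4034. With it p53 targets at 10 µM were not called (adjusted p = 0.0505), nor were 15 of the 383 gene results. Among these were GPER1 (0.0757), AHR (0.0837), THRA (0.0681), PALB2 (0.0888) and XRCC3 (0.0832) at 10 µM, THRA (0.0622) at 1 µM, and XRCC3 (0.091), NBN (0.0571), RMI1 (0.128), TOP3A (0.136) and PPARG (0.0501) between the doses. Deviations of arrays with the same number correlated at 0.12 and 0.04 (control and 10 µM) and at 0.17 and -0.18 (10 and 1 µM). For control and 1 µM the correlation was 0.64, a single value because each group held 2 arrays. An effect shared by equal replicate numbers of control and 1 µM therefore stays open. The main fit, planned without a replicate block, did not take the numbers as pairs. Genes near the dim limit, such as ESR2, have little signal over background. In the simulated data with 200 changed genes, 30.8% of the genes changed by 0.5 on the log2 scale were called at 10 µM, a share that depends on how many genes change.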

Other observations

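The tests of neighbouring genes in this part were chosen only after the results were seen.

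Lists without a call at either dose against control still held single genes with large changes. Enzymes of xenobiotic metabolism fell in 9 of 18 cases and rose in 2 at 10 µM (camera adjusted p = 0.0619), among them CYP1A1 (-2.41 ± 0.14), the classic target of the aryl hydrocarbon receptor, and CYP3A5 (lower by at least 3.44). Antigen presentation genes fell in 9 of 14 and rose in 2 (TAP1 -1.80 ± 0.10, HLA-E -1.43 ± 0.18; adjusted p = 0.0564). Polycomb and chromatin genes fell in 11 of 20 and rose in 7 (adjusted p = 0.501), with the methyltransferase gene EZH2 up by 2.26 ± 0.12 and its relative EZH1 at -2.65 ± 0.11. Mesenchymal genes rose in 9 of 24 and fell in 8 (FBN1 4.98 ± 0.13, FN1 4.42 ± 0.15; adjusted p = 0.973). Matrix proteolysis genes rose in 8 of 21 and fell in 4 (SERPINE2 3.57 ± 0.14, TIMP3 -3.25 ± 0.14; adjusted p = 0.741). Laminin, collagen and integrin genes rose in 10 of 28 and fell in 10 (COL12A1 5.24 ± 0.16, LAMB1 -3.04 ± 0.14; adjusted p = 0.797). Inflammatory cytokines rose in 11 of 22 and fell in 8 (CXCL5 at least 5.12, IL24 lower by at least 2.89; adjusted p = 0.676). Immediate-early genes rose in 9 of 22 and fell in 7 (DUSP6 at least 4.94, ZFP36 -2.62 ± 0.12; adjusted p = 0.719). In signalling, the Notch target HES1 rose by 3.84 ± 0.15 while 10 of 18 Notch genes were not called (adjusted p = 0.996). In the Wnt list WNT5A rose by 2.28 ± 0.15 and FZD2 fell by 2.94 with 11 of 21 not called (adjusted p = 0.996).

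Metabolic and stress lists at 10 µM were mixed: fatty acid genes rose in 6 of 15 and fell in 6 (SCD 2.61 ± 0.13; adjusted p = 0.914), oxidative stress genes in 9 and 7 of 25 (FTL -2.55 ± 0.15; adjusted p = 0.981) and unfolded protein genes in 13 and 10 of 30 (VLDLR at least 1.93; adjusted p = 0.676). Heat shock genes rose and fell in 6 and 4 of 14 (HSPH1 2.03 ± 0.16; adjusted p = 0.676) and oxidative phosphorylation genes in 11 and 5 of 33 (adjusted p = 0.71). Of the repair lists, nucleotide excision repair genes rose in 6 of 22 and fell in 5 (adjusted p = 0.981) and end joining genes in 7 and 3 of 13 (PRKDC 1.33 ± 0.11; adjusted p = 0.315). Mismatch repair was not tested as a list, and MSH6 rose by 0.84 ± 0.11. Oestrogen response genes rose in 6 of 21 and fell in 5 (camera adjusted p = 0.741), with a median of -0.01 and a mean of 0.38. Among them CA12 gave -3.11 ± 0.15, while AGR2 rose by at least 3.75 and FOXA1 by at least 2.16. This list averaged 7.818 in controls, 8.198 at 10 µM and 8.549 at 1 µM, and was not called at either dose against control. HOX genes rose in 3 of 15 and fell in 1 (adjusted p = 0.653), and at 1 µM in 6 and 1 (HOXB3 1.54 ± 0.15; adjusted p = 0.29). Adjusted over the list alone, 5 excision repair, 9 oxidative phosphorylation, 2 HOX, 8 polycomb, 17 glycolysis and 4 leukocyte genes were higher, and the other counts given for lists at 10 µM were the same. Base excision repair genes rose in 9 of 19 and fell in 3 (FEN1 4.48 ± 0.13; adjusted p = 0.172), Fanconi anaemia genes in 7 and 2 of 10 (FANCI 3.29 ± 0.12; adjusted p = 0.151). Basal markers rose and fell in 8 and 5 of 18 (adjusted p = 0.691), epidermal genes in 11 and 4 of 18 (adjusted p = 0.108), and glycolysis and hypoxia genes in 16 and 5 of 30 (adjusted p = 0.14). Marker lists of fibroblasts (2 higher and 2 lower of 7; adjusted p = 0.914), leukocytes (3 and 2 of 7; adjusted p = 0.96), endothelium (2 and 1 of 6; adjusted p = 0.719) and hepatocytes (0 and 2 of 5; adjusted p = 0.448) were not called, and of the untested neural markers TUBB3 rose by 3.40 ± 0.37. The median, mean and test direction of a list differed in sign at 10 µM for the oestrogen, fatty acid, immediate-early, Wnt, Notch and leukocyte lists, and at 1 µM for the basal, proteolysis, cytokine, unfolded protein, heat shock and laminin lists, none of them called there.

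Ordered along the chromosomes, genes on chromosome 1 formed 4 runs at 1 µM, of which the 2 longest were kept (the others held 2 genes each): from RPL22 to SRM (46 genes) and from LBR to KCNK1 (61 genes), whose 107 genes had medians of -0.68 at 1 µM and -0.61 at 10 µM (83.2% and 76.6% lower, against 48.2% and 47.1% of all genes). Chance order is argued against by the whole search at 1 µM: its largest running median anywhere in the genome was -0.778, in the first run, and that of the second run was -0.739, while the largest anywhere in each of 200 shuffled orders reached at most 0.6146 on either side (limit used for the runs 0.5101). Dim probe sets stay open: the 54 brighter genes of the runs had a median of -0.7574 at 1 µM, but they had been picked for being lower, and a search of the brighter 6902 genes alone with a window of 25 gave a lowest value of -0.8537 in the weaker region, within its wider limit of 1.024. A copy number difference between the control cells and both treated populations may be a cause: the doses differed by a median of only 0.04111 over these genes, within the range of -0.0537 to 0.101 of 1000 random sets, so most sets of genes would also give this value. DNA copy number was not measured here, and regulation of neighbouring genes in RNA stays open.

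At 10 µM the search passed its limit of 0.5929 in only parts of these regions, mainly from TNFRSF25 to UBE4B (30 genes, lowest running median -0.7325) and from COQ8A to LINC02809 (7 genes, -0.6223). Runs elsewhere were shorter. They included 3 genes from ZNF204P to ZNF184 on chromosome 6 at 10 µM (-0.6147) and 6 genes from GATAD1 to VPS50 on chromosome 7 at 1 µM (0.5686). Between the doses the longest was on chromosome 7, from TMEM243 to BET1 (23 genes, -0.4786, limit 0.3119).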
